A study of Mus musculus with 6 samples.

How the data were processed

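RNA of 6 mouse embryonic fibroblast samples was extracted with Trizol, cleaned up, amplified to biotin-labelled cRNA and hybridised to Illumina mouse bead arrays of 1 slide, per the labels' protocols. With 1 slide for all arrays, slide effects could not be tested. The authors deposited a table of non-normalized intensity values with a detection p-value for each probe and array. They also deposited log2 values of the same arrays, for which the submitters' processing notes name limma without a version. The background correction and normalization of those log2 values are not given in the sources used here. Set against the intensities, the authors' log2 values differed by at most 0.0039 in each group's mean from quantile-normalized log2 intensities without background correction. They were therefore taken as log2, not centred, with no sign change. Their column medians were all 6.54. No scale or direction of these values stayed unknown.

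Intensity columns carry a genotype and a letter but no replicate number, so they were assigned to their genotype only. The 3 wild-type columns are called arrays A to C and the 3 knockout columns arrays D to F. If the letters follow an order or a position on the slide, its effect could not be told apart from genotype. All 6 arrays entered the comparison. The columns of the authors' log2 values carry replicate numbers 1 to 3, which both genotypes share.

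Background was corrected with normexp, with the negative control mean and SD inferred from the detection p-values, and values were quantile-normalized and put on the log2 scale with an offset of 16 (neqc of limma 3.58.1 in R 4.3.3). The offset makes changes of dim probes smaller than the true ones. A probe was kept if its detection p was below 0.05 on at least 3 of the 6 arrays, whatever the genotype. This kept 19802 of 45281 probes (43.7%). Probes were named from GEO's platform annotation, in which 34885 probes had 1 gene symbol and 18 had several. The other 10378 are unnamed here. Symbols were updated through the Entrez ID in a RefSeq gene table of assembly GRCm38.p6, where 34807 probes matched and 0 symbols differed. That table was also used for the chromosome of each gene, and no coordinates of it are given. A gene was represented by its kept probe with the highest mean over all arrays, which gave 11040 genes, 4149 of them with more than 1 kept probe. Probes were tested with lmFit and eBayes of limma for knockout minus wild type (4 residual and 5.27 prior degrees of freedom), with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05.

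A probe detected on only some arrays of a group has its fitted change given, which is uncertain in size. Among the genes named by the rule, this holds for Car3, Dlx1, Hapln1, Igfbpl1, Lcn2, Lpar2, Meg3, Mup2, Plvap and Trim30a. Where a probe was not detected on any array of a group, its fold is given as a bound. The brighter group's mean was set against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest value among detected probes of that array. The genes named were chosen by a rule fixed before the data were examined: Lpar6; the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, without clone names; and up to 4 called members with the largest change of each list. For the lists on LPA receptors, LPA synthesis, Y-linked genes and chromosome 14 neighbours, 2 members would have been named without a call. The rule gave 162 genes, all called. Of the named genes, 62 had more than 1 kept probe, and in 11 of these, counting members not reported here, a further kept probe did not pass. Lpar4 and Sox10, and the members of lists added later, are named outside the rule, after their values were seen. The result of 1 list and its members is not reported here.

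Gene lists were tested on the representative probes with camera at a preset correlation of 0.01, 2-sided, with adjustment over the lists with at least 5 kept genes. The correlation estimated for each list and fry were alternatives. Called shares on chromosome 14 were compared with Fisher's exact test. Alternatives fixed before the data were examined covered plain log2 values with an offset of 50, median scaling, cyclic loess, the authors' values, an offset of 50 in neqc, no filter on detection, detection p below 0.01 on all 6 arrays, the mean of a gene's probes, eBayes with trend and robust, array weights, other thresholds, replicate numbers as a block, and leaving out each array in turn. The block could be run only together with the authors' values, a combination added after the data were seen, as were some of these alternatives for the lists.

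The steps were tested on simulated data made from the wild-type means and the probes' own spread, with 200 changed probes among 19829 tested. The changed probes were drawn only from the brighter kept probes, so recovery of changes in dim probes was not tested. For knockout minus wild type, 28.8% of simulated log2 changes of 0.5, 89.6% of those of 1 and 100% of those of 2 were recovered, with 10 false calls among 156. Of 30 simulated unshifted lists of independent genes 0 passed camera, and a shifted list of 20 genes did. In the real data 37.9% of kept probes were called, and genes of a list can be correlated. The simulation therefore does not show how normalization or camera behave under so broad a change or with correlated genes. No array was left out of the main comparison. The number of arrays limits the precision, and bead counts behind each intensity were not used here.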

Results

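Transcript levels were measured in mouse embryonic fibroblasts, the primary cells that grow out of dissociated embryos, from a mixed 129SV and C57BL/6 background. The comparison asks how the transcripts of fibroblasts without Lpar6 differ from those of fibroblasts that carry it; Lpar6 encodes a receptor for lysophosphatidic acid (LPA), a lipid signal. There were 3 Lpar6+/+ arrays (wild type, columns A to C) and 3 Lpar6-/- arrays (knockout, columns D to F), all Illumina bead arrays of 1 slide. The submitters' title speaks of a knock-down, while their genotype labels name Lpar6-/- cells; the genotype labels were followed. Of the 45281 probes, 19646 to 20137 were detected on the wild-type arrays and 19006 to 19249 on the knockout arrays at the detection p threshold of 0.05. Correlations across the kept probes were 0.995 within the wild type, lay between 0.993 and 0.994 within the knockout and between 0.966 and 0.968 across genotypes. The labels do not say that the replicates came from separate embryos or cultures, so that p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. Changes below are knockout minus wild type on the log2 scale ± SE, with 3 arrays in each group, unless given as a bound.

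The Lpar6 transcript was present on the wild-type arrays and was not well above background on any knockout array. Its only probe (ILMN_2792601) had intensities of 1373, 1223 and 1278 on the wild-type arrays and of 76.7, 77.9 and 76.0 on the knockout arrays, where the detection p was 0.893, 0.76 and 0.738. The level was at least 37.5-fold lower in the knockout (limma, adjusted p = 1.51e-09). The size of this bound depends on the scale: it was 18.5-fold with an offset of 50 after background correction and 8.64-fold for plain log2 values with an offset of 50. Whether the probe lies inside the deleted part is not given in the sources used here. Of the other LPA receptors with a kept probe, Lpar2 was lower (-0.91 ± 0.16) and Lpar1 was higher (0.40 ± 0.086). Lpar2 was detected on only 2 knockout arrays, so the size of its fall is uncertain. The fourth kept receptor, Lpar4, had a change of -0.24 that did not pass the threshold over all probes and did pass adjusted over the list alone (1 higher and 3 lower). The rise of Lpar1 did not pass under median scaling (0.26, adjusted p = 0.084), with limma adjusted p of 0.00049 to 0.084 over 17 alternatives. With 4 kept members the receptor list was too short for the list test. Of the 10 kept genes of the fixed list named LPA synthesis and breakdown, 3 rose and none fell: Pnpla2 (1.62 ± 0.10), Agpat2 (0.66 ± 0.15) and Pla1a (0.35 ± 0.10). Adipocyte markers, with a median of 1.40, were higher on the same arrays. A change in LPA itself was not measured, and membership of the list does not show that a gene acts on LPA. The LPA synthesis list as a whole did not pass (camera adjusted p = 0.132), though it did without the detection filter (0.0307) and with the mean of each gene's probes (0.0463). The call of Pla1a was lost without wild-type array B, wild-type array C or knockout array D, with limma adjusted p = 0.0544, 0.0707 and 0.0624, and under median scaling with 0.312. Its lowest adjusted p over 17 alternatives was 0.0047.

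Beyond the targeted gene, adipocyte genes rose in the knockout, and neuronal and cartilage genes fell. The largest rise was that of Adipoq, the adipocyte hormone adiponectin, which was not detected on any wild-type array and was at least 53.98-fold higher. It was followed by the haemoglobin-binding plasma protein gene Hp (4.57 ± 0.10), the carbonic anhydrase gene Car3 (4.47 ± 0.14), the lipid droplet gene Cidea (at least 10.8-fold higher) and Lrg1 (at least 9.65-fold higher). Mup2 (3.47 ± 0.12), Apoc1 (3.36 ± 0.095), Aoc3 (2.80 ± 0.091), Lcn2 (2.72 ± 0.090), C4a (2.69 ± 0.13), S100a8 (2.66 ± 0.10) and Cox7a1 (2.64 ± 0.13) completed the 12 largest rises; S100a8 and Lcn2 encode proteins abundant in neutrophils, and Cox7a1 a respiratory chain subunit of heart and muscle. After Lpar6, the largest falls were those of Sall3 (-3.37 ± 0.096), Lamp5 (-3.30 ± 0.096), Ina (-3.19 ± 0.13), Rbfox3 (-3.17 ± 0.13) and Mapt (-3.13 ± 0.11). Sst (-3.09 ± 0.12), B3gat1 (-3.09 ± 0.086), Dcx (-2.999 ± 0.095), Miat (-2.99 ± 0.086), Gad1 (-2.99 ± 0.094) and Igfbpl1 (-2.98 ± 0.10) followed. Ina, Rbfox3, Mapt and Dcx are neuronal structural or nuclear markers, Sst encodes somatostatin and Gad1 the enzyme that makes the transmitter GABA. By the rule that chose them, all of these genes had 3 knockout values on one side of the 3 wild-type values. Bounds carry no order among themselves, and their sizes depend on the scale, as that of Lpar6 does. Mup2 and C4a have near-identical copies, so the gene behind those probes is uncertain. Lcn2 was detected on only 1 wild-type array and Car3 and Mup2 on 2, so the sizes of their rises are uncertain.

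**Figure D1:**
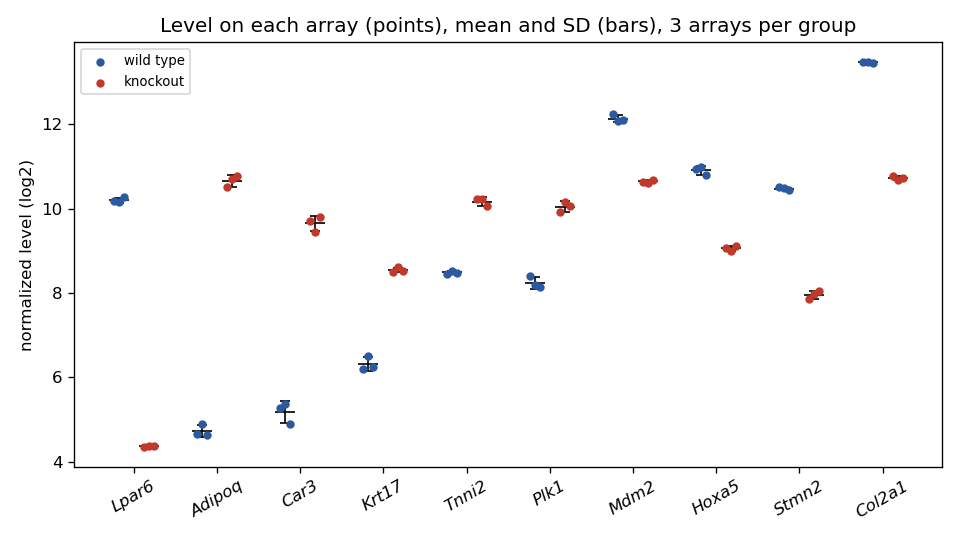
Normalized log2 level (vertical axis) of 10 genes named in the text on each of the 3 wild-type arrays (blue points) and 3 knockout arrays (red points); bars give the mean and SD. The 3 knockout values lie on one side of the 3 wild-type values for each of these genes, and Lpar6 on the knockout arrays and Adipoq on the wild-type arrays were not detected above background.

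In all, 4379 of 11040 genes (39.7%) passed limma's test at an adjusted p threshold of 0.05, 2273 higher and 2106 lower in the knockout. Over probes, 7510 of 19802 passed (3819 higher and 3691 lower). The median size of the change among the called genes was 0.538. A change of at least 2-fold was found in 750 called genes, 264 higher and 486 lower. The groups did not overlap in 52.8% of all kept genes, where chance gives 10%. Of the called genes, 180 were not detected on any knockout array and 80 on any wild-type array. The detection filter keeps such genes only if they are detected on all 3 arrays of the other genotype, which fixes their direction. In 54 called genes, called probes of the same gene moved in opposite directions; none of the genes chosen by the naming rule was among them. A gene's value is that of its brightest kept probe. Among the genes reported here, a further kept probe did not pass for Col3a1, Dusp4, Esd, Foxp2, Kdm3a, Lmnb1, Mmp13, Pfkp, Pla1a and Psmb8, and passed with a change more than 1 smaller on the log2 scale for Gad1 (-0.86), Igfbpl1 (-0.65), Mapt (-0.44), Mup2 (1.48), Sall3 (-2.10) and Thy1 (0.44). The split by direction depended on the scaling: with median scaling in place of quantile normalization, 1393 genes were higher and 2713 lower, and the median change of all genes was -0.082 in place of 0.027. An exact test of 1 gene alone, 3 arrays against 3, cannot give a p below 0.1.

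**Figure D2:**
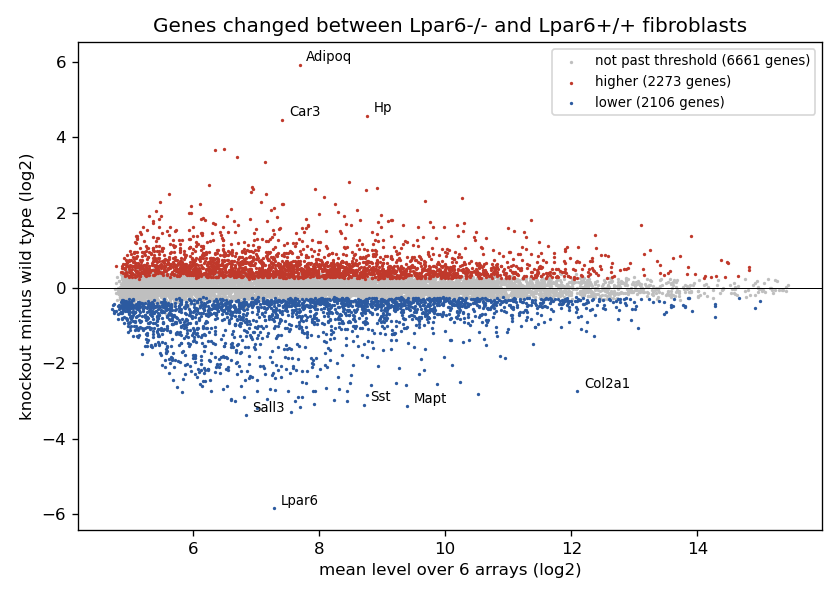
Change between knockout and wild type (vertical axis, log2) against the mean level over the 6 arrays (horizontal axis, log2) for each of the 11040 kept genes; red points are the 2273 genes that passed the threshold and were higher, blue points the 2106 that were lower, and grey points did not pass. Adipoq lies highest and Lpar6 lowest.

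Of the 39 gene lists fixed before the data were examined, 37 had at least 5 kept genes and 16 of these passed the list test (camera), 10 upward and 6 downward. Of the 16, 8 also passed with a correlation estimated for each list. Markers of cell types other than fibroblasts moved in both directions. Adipocyte genes rose in 10 of 11 kept members, with a median change of 1.40 (camera adjusted p = 2.47e-07, and adjusted p = 0.034 with an estimated correlation). Beside Adipoq these were led by the lipid droplet genes Cidec (at least 2.54-fold higher) and Plin4 (1.65 ± 0.093) and by the hormone leptin, Lep (1.46 ± 0.10). Skeletal and cardiac muscle genes rose in 17 of 22, with none lower over all probes (camera adjusted p = 1.79e-07, and adjusted p = 0.034 with an estimated correlation). The largest were the muscle creatine kinase gene Ckm (at least 2.56-fold higher) and the contractile protein genes Tnni2 (1.67 ± 0.091), Myh8 (1.61 ± 0.094) and Tnnt3 (1.33 ± 0.084). Adjusted over the list alone, 18 muscle genes were higher and 1 lower. Epithelial genes rose in 13 of 15, led by the keratin gene Krt17 (2.23 ± 0.10), the tight junction genes Cldn4 (1.60 ± 0.10) and Cldn6 (1.48 ± 0.094) and the splicing regulator Esrp1 (at least 2.00-fold higher). Their list passed the test with the preset correlation (camera adjusted p = 1.79e-07) but not with the estimated one (adjusted p = 0.054 with an estimated correlation). Without background correction the medians were smaller, and each of these lists still passed: under the authors' values 0.68 for adipocyte, 0.52 for epithelial and -0.59 for cartilage genes, and under plain log2 values 0.54, 0.41 and -0.44. Of the genes named here, Adipoq, Cidec, Ckm and Esrp1 were not detected on any wild-type array. The detection filter kept them only through the knockout arrays, which fixed their direction. With detection asked on all 6 arrays, which leaves such genes out, the adipocyte median was 0.69 and that list still passed.

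Neuronal and cartilage genes fell. Of 9 kept genes of the list of neurons, glia and neural crest, 7 were lower, with a median change of -1.30 (camera adjusted p = 3.76e-05, and adjusted p = 0.048 with an estimated correlation). The largest falls were in the microtubule-associated genes Dcx (-2.999 ± 0.095), Stmn2 (-2.51 ± 0.091) and Map2 (-2.18 ± 0.10) and in the RNA-binding protein gene Elavl3 (-2.90 ± 0.14). The median was -0.10 without the detection filter and -0.86 under plain log2 values, and the list passed in both. Sox10, a neural crest and glial regulator, was the 1 member that rose (0.30). Cartilage and bone genes fell in 13 of 18, with 1 higher (camera adjusted p = 6.13e-07, and adjusted p = 0.034 with an estimated correlation). Col2a1, the main collagen of cartilage, fell by 2.74 ± 0.084 from a wild-type mean of 13.47 to 10.73. It was joined by the cartilage matrix genes Matn1 (-2.05 ± 0.12), Snorc (-2.04 ± 0.098) and Hapln1 (-1.71 ± 0.14). Hapln1 was detected on only 1 knockout array, so the size of its fall is uncertain. Over the list of macrophage and blood genes, 5 of 17 fell and 2 rose, and the list did not pass (camera adjusted p = 0.351). The members that fell were led by the embryonic globin gene Hbb-y (-1.82 ± 0.10) and by Hba-a1 (-1.02 ± 0.087) and Fcer1g (-0.73 ± 0.11); C1qa (0.58 ± 0.14) was higher, a call not made under median scaling (adjusted p = 0.051, with a lowest of 0.000488 over 17 alternatives). Hba-a1 has a near-identical copy, so that its value is uncertain. Smooth muscle and pericyte genes rose in 8 of 14 and fell in 2 (camera adjusted p = 0.0792), with Myh11 (0.80 ± 0.11), Abcc9 (0.79 ± 0.12), Kcnj8 (0.78 ± 0.15) and Des (0.67 ± 0.096) the largest. Endothelial genes moved both ways, 3 of 9 higher and 1 lower (camera adjusted p = 0.338): Egfl7 (0.62 ± 0.085), Plvap (0.56 ± 0.11), Tek (-0.48 ± 0.11) and Flt1 (0.42 ± 0.085). Of 5 kept placental and germ cell genes, Esrrb (at least 1.23-fold lower) was the 1 that fell (camera adjusted p = 0.574).

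**Figure D3:**
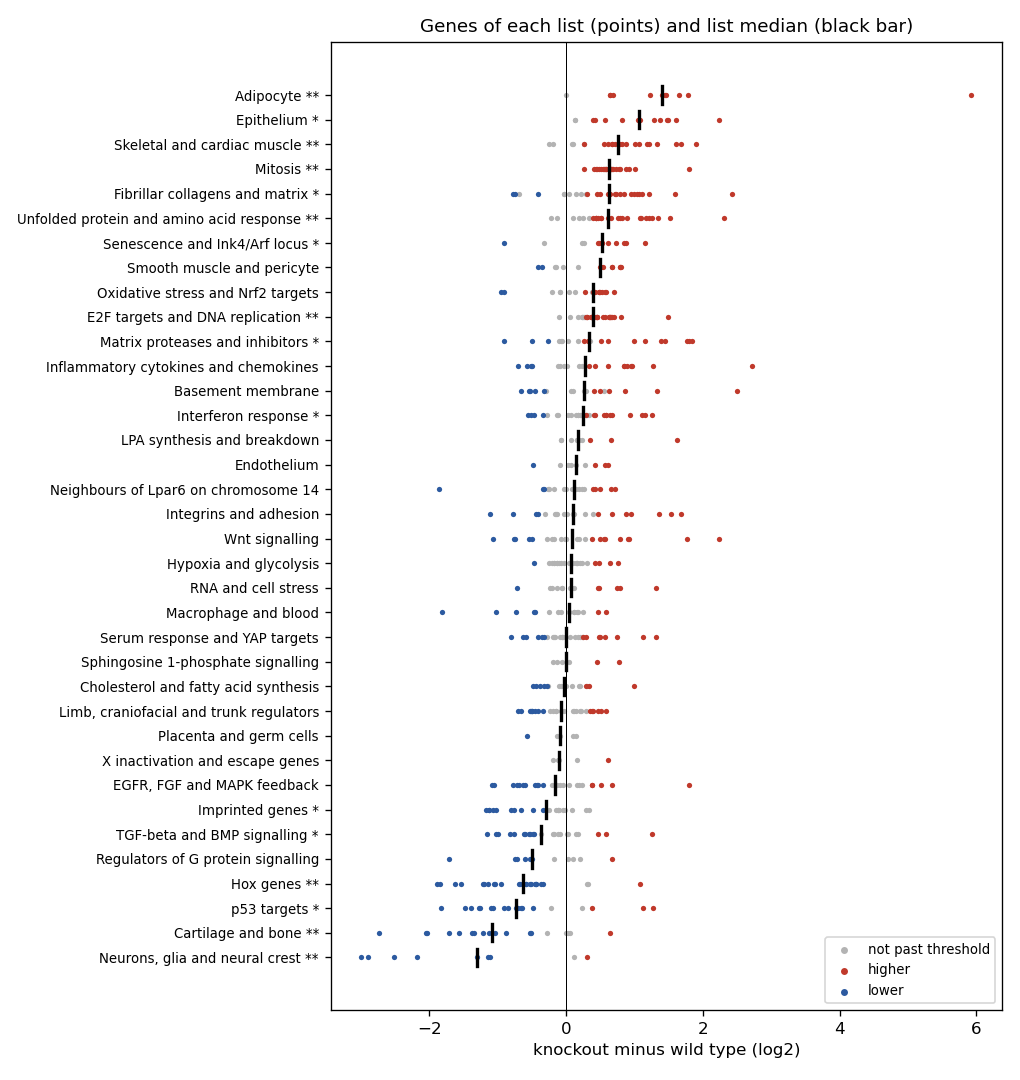
Change between knockout and wild type (horizontal axis, log2) of every kept gene (points) in 36 of the 37 tested lists, with each list's median as a black bar; red and blue points passed the threshold upward and downward. A list with 1 asterisk passed camera with the preset correlation, and a list with 2 asterisks also with the estimated one; adipocyte genes have the highest median (1.40) and neuronal genes the lowest (-1.30).

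Genes of cell division rose together, on the same arrays as the shifts of adipocyte, neuronal and cartilage markers. All 22 kept mitosis genes were higher, with a median change of 0.62 (camera adjusted p = 1.25e-08, and adjusted p = 0.034 with an estimated correlation). The mitotic kinase gene Plk1 (1.80 ± 0.11) led, followed by the centriole duplication kinase gene Plk4 (1.003 ± 0.13), the kinesin gene Kif23 (0.92 ± 0.10) and the phosphatase gene Cdc25c (0.88 ± 0.098). Of 33 kept E2F target and DNA replication genes, 22 were higher and none lower (camera adjusted p = 3.78e-07, and adjusted p = 0.04 with an estimated correlation), among them E2f2 (1.49 ± 0.15), Tk1 (0.81 ± 0.098), Chaf1b (0.70 ± 0.083) and Pole (0.67 ± 0.088). Genes activated by the tumour suppressor p53 went the other way, with 14 of 19 lower and 3 higher. The falls were led by Pidd1 (-1.82 ± 0.12), Mdm2 (-1.49 ± 0.089), Trp53inp1 (-1.39 ± 0.089) and Ccng1 (-1.27 ± 0.10); Mdm2 encodes the ligase that degrades p53. The p53 list passed with the preset correlation (camera adjusted p = 7e-05) but not with the estimated one (adjusted p = 0.11 with an estimated correlation). The list of senescence genes and the Ink4/Arf locus was higher in 9 of 13 and lower in 1 (camera adjusted p = 0.00637, and adjusted p = 0.10 with an estimated correlation). Its largest members were the secreted factors Mmp3 (1.16 ± 0.11), Mmp13 (-0.91 ± 0.100) and Igfbp7 (0.88 ± 0.13) and the nuclear lamina gene Lmnb1 (0.85 ± 0.10), whose loss, not gain, is known from senescent cells.

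Of 27 kept genes of the unfolded protein and amino acid response, 21 rose and none fell (camera adjusted p = 5.31e-08, and adjusted p = 0.034 with an estimated correlation). The largest rises were in Trib3 (2.31 ± 0.11), Nupr1 (1.52 ± 0.095) and Chac1 (1.35 ± 0.098), targets of the stress regulator ATF4, and in the serine synthesis gene Phgdh (1.26 ± 0.095). Interferon response genes were higher in 12 of 31 and lower in 4 (camera adjusted p = 0.0278, and adjusted p = 0.11 with an estimated correlation). The largest were Ifi27l2a (1.26 ± 0.11) and Trim30a (1.15 ± 0.14) and the immunoproteasome genes Psmb8 (1.10 ± 0.093) and Psmb9 (0.93 ± 0.19); the list's call was lost without knockout array D (adjusted p = 0.0574) and with detection asked on all 6 arrays (0.108), and the lowest adjusted p over 17 alternatives was 0.0155. On the same arrays adipocyte markers were higher, with a median of 1.40. Inflammatory cytokines and chemokines were higher in 10 of 20 and lower in 4 and did not pass (camera adjusted p = 0.0629), with Cxcl1 (1.27 ± 0.10), Ccl7 (0.97 ± 0.088) and Ccl11 (0.95 ± 0.12) the largest after Lcn2. Oxidative stress genes were higher in 11 of 19 and lower in 2 (camera adjusted p = 0.0792); the 2 that fell, Ephx1 (-0.95 ± 0.100) and Nqo1 (-0.90 ± 0.089), were also the largest changes, before Gstm2 (0.70 ± 0.086) and Sod2 (0.58 ± 0.11). In the list of RNA and cell stress, 5 of 14 rose and 1 fell (camera adjusted p = 0.411), with the largest changes in Ier2 (1.31 ± 0.096), Ddit3 (0.79 ± 0.10), Junb (0.75 ± 0.086) and Dusp1 (-0.71 ± 0.092).

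Collagens and matrix genes, the main products of fibroblasts, were higher in 18 of 28 and lower in 3, with a median of 0.62 (camera adjusted p = 7e-05, and adjusted p = 0.11 with an estimated correlation). The microfibril gene Mfap5 (2.42 ± 0.085) and the collagen genes Col6a2 (1.59 ± 0.11), Col3a1 (1.21 ± 0.10) and Col1a2 (1.11 ± 0.15) changed most by their brightest probes; the other kept Col3a1 probe gave 0.15 and did not pass. Epithelial and muscle markers, with medians of 1.07 and 0.75, were higher on the same arrays. Matrix proteases and their inhibitors were higher in 11 of 20 and lower in 3 (camera adjusted p = 0.00637, and adjusted p = 0.099 with an estimated correlation), led by Mmp9 (1.84 ± 0.16), Ctsk (1.79 ± 0.099), Adamts4 (1.77 ± 0.14) and Mmp11 (1.45 ± 0.10). Basement membrane genes went both ways (6 higher and 5 lower of 17, camera adjusted p = 0.308), with Col15a1 (2.50 ± 0.11), Col18a1 (1.32 ± 0.090) and Col4a2 (0.86 ± 0.11) higher and Col4a5 (-0.67 ± 0.13) lower. Integrins and adhesion genes were higher in 7 and lower in 4 of 22 (camera adjusted p = 0.351), with Thy1 (1.68 ± 0.099), Itga7 (1.53 ± 0.11) and Itga11 (1.37 ± 0.100) higher and Alcam (-1.11 ± 0.087) lower.

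Hox genes, which mark position along the body axis, fell in 21 of 24 kept members and rose in 1 (camera adjusted p = 1.15e-07, and adjusted p = 0.048 with an estimated correlation). The largest falls were in Hoxb5 (-1.90 ± 0.10), Hoxa5 (-1.84 ± 0.093), Hoxb6 (-1.62 ± 0.100) and Hoxd10 (-1.54 ± 0.099). The median was -0.63, and -0.41 under the authors' values and -0.37 under plain log2 values. On these arrays neuronal markers, with a median of -1.30, were lower too. Other limb, craniofacial and trunk regulators went both ways, 6 higher and 9 lower of 27 (camera adjusted p = 0.435). Tbx2 (-0.70 ± 0.099), Foxp2 (at least 1.33-fold lower) and Dlx2 (at least 1.20-fold lower) were lower and Dlx1 (0.58 ± 0.16) was higher; the call of Dlx1 was lost without wild-type array A, wild-type array C or knockout array F, with adjusted p = 0.0668, 0.0681 and 0.0608, the lowest over 16 alternatives being 0.00655. Imprinted genes fell in 10 of 20 and none rose (camera adjusted p = 0.000876, and adjusted p = 0.062 with an estimated correlation), among them Nnat (-1.17 ± 0.087), Meg3 (-1.13 ± 0.14), Phlda2 (-1.12 ± 0.11) and Usp29 (-1.06 ± 0.14). Meg3 was detected on only 1 knockout array, so the size of its fall is uncertain. The list's median of -0.29 was -0.12 without the detection filter and -0.15 with detection asked on all 6 arrays.

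Among signalling lists, TGF-beta and BMP genes fell in 11 of 23 and rose in 3 (camera adjusted p = 0.0154, and adjusted p = 0.11 with an estimated correlation). The growth factor genes Bmp4 (-1.16 ± 0.087) and Tgfb2 (-1.003 ± 0.096) and the BMP target Id1 (-1.03 ± 0.094) were lower, while the receptor gene Tgfbr3 (1.25 ± 0.089) was higher. The median of -0.37 was -0.24 without knockout array D, and the list still passed. Cartilage and neuronal markers, with medians of -1.08 and -1.30, were lower on the same arrays. Serum response and YAP targets did not pass as a list (8 higher and 6 lower of 28, camera adjusted p = 0.747); Ier2 (1.31 ± 0.096), Fosb (1.13 ± 0.093) and Junb (0.75 ± 0.086) were higher and Ankrd1 (-0.81 ± 0.096) lower. Regulators of G protein signalling were lower in 6 of 11 and higher in 1 (camera adjusted p = 0.0629), with Rgs7 (-1.71 ± 0.10), Rgs17 (-0.75 ± 0.11) and Rgs12 (-0.72 ± 0.10) lower and Rgs5 (0.67 ± 0.093) higher. Wnt genes (9 higher and 5 lower of 24, camera adjusted p = 0.351) included Lgr5 (2.24 ± 0.11), Ccn5 (1.76 ± 0.088) and Nkd2 (0.92 ± 0.11), higher, and Wnt2 (-1.06 ± 0.11), lower. Genes of the EGFR, FGF and MAPK feedback list were higher in 5 and lower in 11 of 25 (camera adjusted p = 0.11). The hormone gene Fgf21 (1.80 ± 0.12) was higher, and Dusp4 (-1.09 ± 0.094), Etv4 (-1.06 ± 0.086) and Fgfr2 (-0.77 ± 0.090) were lower. Sphingosine 1-phosphate genes rose in 2 of 6, Sgpp1 (0.77 ± 0.10) and Sphk1 (0.45 ± 0.099) (camera adjusted p = 0.659). Hypoxia and glycolysis genes rose in 4 of 22 and fell in 1 (camera adjusted p = 0.574): Ndrg1 (0.76 ± 0.11), Pdk1 (0.64 ± 0.12), Pfkp (0.48 ± 0.10) and Kdm3a (-0.47 ± 0.11). Genes of cholesterol and fatty acid synthesis rose in 3 and fell in 5 of 19 (camera adjusted p = 0.735), with Scd1 (0.999 ± 0.099) higher and Msmo1 (-0.48 ± 0.092), Elovl6 (-0.45 ± 0.12) and Hsd17b7 (-0.38 ± 0.089) lower; the call of Elovl6 was lost without wild-type array A, wild-type array C or knockout array F, with adjusted p = 0.0637, 0.0594 and 0.0587, the lowest over 17 alternatives being 0.000144. The median and the mean of the sphingosine 1-phosphate list differed in sign (-0.01 and 0.15), as did those of the macrophage and blood list (0.04 and -0.18) and the list of X inactivation and escape genes (-0.11 and 0.07). The sign of the first median changed without wild-type array C (0.04), knockout array E (0.01) or knockout array F (0.03), and that of the second without wild-type array A (-0.05) or knockout array E (-0.02). With undetected genes at their bound, the list medians were 1.23 for adipocyte genes, 1.00 for epithelial genes, 0.75 for muscle genes, -1.30 for neuronal genes and -1.005 for cartilage genes. Adjusted over the list alone, 27 of the 39 lists had the same counts of higher and lower genes as over all probes. The counts differed for LPA receptors (1 higher and 3 lower), serum response and YAP targets (8 higher and 7 lower), E2F targets and DNA replication (25 higher and 0 lower), p53 targets (4 higher and 15 lower), senescence and Ink4/Arf locus (11 higher and 2 lower), basement membrane (8 higher and 6 lower), matrix proteases and inhibitors (12 higher and 3 lower), integrins and adhesion (8 higher and 4 lower), TGF-beta and BMP signalling (3 higher and 12 lower), Wnt signalling (10 higher and 5 lower), limb, craniofacial and trunk regulators (7 higher and 9 lower) and skeletal and cardiac muscle (18 higher and 1 lower).

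Because a knockout allele made in cells of 1 strain carries neighbouring alleles with it on a mixed background, the neighbours of Lpar6 on chromosome 14 were counted apart. Of 20 kept neighbours, 8 were called (40%), against 39.7% of the other kept genes (odds ratio 1.01, 2-sided Fisher's exact test over genes, p = 1). Esd stood out at -1.85 ± 0.10 by its brightest probe, but its 4 kept probes differed in size: the other 3 gave -0.52, -0.17 and -0.16, of which only the first passed the threshold. Phf11d (0.71 ± 0.090), Ebpl (0.65 ± 0.092) and Dleu2 (0.50 ± 0.098) were higher. Over all of chromosome 14, 181 of 380 kept genes were called (47.6%), against 39.4% elsewhere (odds ratio 1.40, Fisher's exact test, p = 0.00135). Genes are not independent replicates in either test. No coordinates were used, so how near the listed neighbours lie to Lpar6 was not checked, and the first test may include distant genes.

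Genes that tell the sexes apart were present together. Xist, the RNA of the inactive X chromosome, and the Y-linked genes Eif2s3y and Kdm5d were each detected on all 3 wild-type and all 3 knockout arrays. In the knockout, Xist was higher (0.61 ± 0.14) and Kdm5d (-0.84 ± 0.17) and Eif2s3y (-0.63 ± 0.16) were lower. All 4 kept Xist probes were higher. Whether the mix of male and female cells differed between the genotypes was not tested. Effects of such a difference on other genes could not be told apart from those of the genotype. The call of Eif2s3y was lost without wild-type array B or C (adjusted p = 0.0525 and 0.0544), the lowest over 17 alternatives being 0.0002. The other 4 kept genes of the list of X inactivation and escape genes did not pass, and the list did not pass (camera adjusted p = 0.975).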

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

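The look at probes without a gene name was chosen after the main results were seen. The comparisons of genes leave out probes that carry no gene name here, and a signal appeared there. Of 2780 such kept probes, 1014 (36.5%) passed the threshold of limma's test between knockout and wild type, a share near the 37.9% of all kept probes. Ranked by the fitted change, which is itself no bound, the highest rise was that of probe ILMN_2835423, which was not detected on any wild-type array, was detected on all 3 knockout arrays and was at least 32.7-fold higher. The deepest fall was that of probe ILMN_1228434, which was detected on all 3 wild-type arrays and on 0 knockout arrays and was at least 9.63-fold lower. No explanation was tested for these probes.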

How the results depend on the processing

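Over 17 alternatives, 2707 comparisons of the 161 named genes other than Lpar6 were made. Of these, 2693 kept their direction and their side of the threshold, 14 lost their call and 0 reversed. The named genes were chosen as called genes with large changes in these same data, which favours a high share kept. Of all 4379 called genes, 3480 to 3783 kept their call and direction when 1 array was left out. Lpar6 was called under the 16 alternatives that could test it; it is not tested where detection is asked on all 6 arrays. Of 701 comparisons of the 37 tested lists, 652 kept both, 10 lost the call, 39 gained one and 0 reversed. Lists gaining a call outside fry were those of G protein regulators, inflammatory cytokines, oxidative stress, smooth muscle, LPA synthesis, Wnt signalling and MAPK feedback. The LPA receptor list passed without the detection filter, where it was long enough to be tested. That list holds Lpar6 itself, the targeted gene, so its call does not show a shift of the other receptors. Alternatives added after seeing the data were the block on the authors' values and, for the lists, median scaling, cyclic loess, an offset of 50, trend with robust, and array weights. With a minimum change of 2-fold, 750 genes were called, 264 higher and 486 lower, and at an adjusted p of 0.01, 2876 with 1430 higher; a stricter threshold leaves fewer by construction. Median scaling gave 1393 genes higher and 2713 lower, and moved the median of all genes to -0.082 from 0.027; the cause was not tested. The 4106 genes called under it included 3410 of the 4379 called genes. With an estimated correlation 8 lists were called, and with fry, which does not compare a list with other genes, 31. The chromosome 14 odds ratio was 1.40 (Fisher's exact test, p = 0.00135) over the whole chromosome, where more genes are tested, against 1.01 for the neighbours.

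Leaving out each array in turn gave 3580 to 4068 called genes, 1848 to 2086 higher and 1711 to 1982 lower, 15 to 18 lists, and odds ratios of 0.686 to 1.27 for the neighbours. The replicate numbers could be used as a block only with the authors' values, since the intensity columns carry none. The deviations of same-numbered samples from their group means correlated at -0.048, 0.020 and -0.054. No sample correlated best with its own number, so the numbers give no sign of a pairing. Between unlike numbers, wild-type samples 3, 1 and 2 correlated at 0.15, 0.0866 and 0.0923 with knockout samples 1, 2 and 3. The remaining pairs gave -0.109, -0.103 and -0.0351. Whether samples were paired in another order was not tested. The replicate block gave 4906 called genes, 2551 higher and 2355 lower, against 4951 without it; it gave 18 lists with and without it and a chromosome 14 odds ratio of 1.02. Signal over background limits changes of dim probes, which have only bounds where a group was not detected.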

Other observations

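The tests in this part use 4 gene lists written after the main results were seen, each without genes already named or listed. The bounds on their medians were written before those medians were seen, while removing Hp and Nnat as already seen and asking that a lower bound be missed by more than the members' spread came after; without that condition both adipocyte explanations would have been argued against. The test of a lower share of fibroblasts and the split counts of genes were chosen after the result was seen.

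Beyond the genes of the fixed lists, 15 further abundant neuronal transcripts were kept, of which 13 were lower in the knockout and 0 higher. They included the kinesin gene Kif5c (-1.98 ± 0.13), the synaptic vesicle gene Syn1 (-1.92 ± 0.11), the granule protein gene Chgb (-1.92 ± 0.13) and Camk2b (-1.63 ± 0.12); Uchl1 (-1.20 ± 0.11) fell less. Among 13 further adipocyte transcripts, 6 were higher and 3 lower. The highest was the triglyceride synthesis gene Dgat2 (1.24 ± 0.10). Of the 6, Aqp7 (at least 1.58-fold), Orm1 (at least 1.47-fold), Lipe (at least 1.47-fold) and Acvr1c (at least 1.36-fold) were not detected on any wild-type array, and the detection filter keeps such genes only if they are detected on all 3 knockout arrays. Of 10 brown adipocyte transcripts, 4 were higher, led by Cpt1b (1.01 ± 0.11) and Kng2 (0.76 ± 0.097), and 4 were lower, led by Zic1 (-1.78 ± 0.087) and Fabp3 (-0.69 ± 0.11). Of 5 neutrophil transcripts, 4 were higher, Ngp (at least 2.20-fold), Pglyrp1 (at least 1.94-fold), Prtn3 (0.80 ± 0.15) and Elane (0.76 ± 0.11), and Clec4d (-0.44 ± 0.090) was lower; the filter likewise fixed the direction of Ngp and Pglyrp1, which were not detected on any wild-type array.

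Chromosome 14 had the highest share of called genes of the 20 chromosomes compared, 47.6% of 380 (Fisher's exact test over genes, adjusted p = 0.0268 over the 20), before chromosome 15 with 44.2% (adjusted p = 0.299). Shares of the others lay between 35.2% and 42.5%. This comparison was added after seeing the data, and genes are not independent replicates.

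Neuronal genes were lower on the knockout arrays. Background correction and normalization as the whole cause are argued against by the neuronal list, whose median stayed at -0.864 or lower under plain log2, median scaling, cyclic loess and the authors' values. One hypothesis is that the wild-type cultures held more RNA of neural cells. Such cells would bring all their abundant transcripts, and the further neuronal transcripts had a median of -1.14; all 15 were detected on the wild-type arrays and 13 on all 6, with wild-type means of 9.27 for Kif5c and 11.50 for Dpysl3. That is in line with this hypothesis, though fibroblasts express several of the 15, and an effect of the genotype on these genes within cells stays open and untested.

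Adipocyte genes were higher on the knockout arrays. A lower share of fibroblasts, if it were the only difference between the cultures, would raise markers of every other type alike. The cartilage list, with a median of -1.08, argues against that as the whole explanation. It cannot exclude a lower share together with other differences in cell types, and the fall of cartilage genes was known when the test was chosen. RNA of adipocytes in the knockout cultures may contribute, but the test did not settle it: the further adipocyte transcripts had a median of 0.337, under the bound of 0.5 by less than the spread of their members (0.735), which went both ways, and 7 of 13 were already detected on all wild-type arrays. For brown adipocytes the median was 0.0513, again with members both ways. That list leaves out genes already named, among them Cidea (at least 10.8-fold higher) and Cox7a1 (2.64), so its median does not decide the question. An effect of the genotype on fat cell formation stays open and was not tested.

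S100a8 and Lcn2, which neutrophils express, were higher on the knockout arrays, 2 genes that no fixed list of neutrophil genes covers. RNA of neutrophils or their precursors is a candidate explanation that these data leave open: the 5 other neutrophil transcripts had a median of 0.802, between the bounds of 0.5 and 1. Haptoglobin (Hp) was first in this list and was taken out because its rise had already been seen; with it the median was 1.03, which would have met the upper bound. Induction of these genes in fibroblasts was not tested.

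The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, called as many as 4379 genes, and the highest of the other 9 called 0. For lists, the real split gave 16, the highest other split 15 and the lowest 7, and again 1 split reached the real value. With an estimated correlation the real split called 8 lists and each of the others 0. Each of the other 9 splits puts arrays of both genotypes in both groups. The genotype difference then adds to the spread within groups, so that 0 called genes was close to fixed beforehand. Their list counts also carry part of the genotype difference, so neither count measures chance.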
